A study of Mus musculus with 6 samples.

How the data were processed

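Gene expression was measured in 6 samples of mouse hybridoma RNA, 3 per group, on Illumina bead arrays of 45281 probes. Per the labels, the hybridomas were kept in RPMI with fetal calf serum, RNA was isolated with a column kit, and biotinylated cRNA was made with an Ambion amplification kit for Illumina arrays. The scanner software and its settings are not given in the sources used here.

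The authors deposited a table without normalization that holds, for each probe and array, the average bead signal intensity on a linear scale. Background settings are not given in the sources used here; as no signal is near or below 0, the signals were read as not background-subtracted, and the background correction rests on that reading. Beside each intensity, the deposited table gives a detection score between 0 and 1. The header calls it a detection p-value, but the score rises with signal and reaches 1 for bright probes, so it was read as 1 minus the detection p-value. A second table of the authors, deposited as the processed values, holds intensity on a linear scale. Nearly all sorted values of its 6 columns lie within 0.0727% of the mean of the sorted signals, and the column medians are 66.7. These values were therefore found to be quantile normalized over all probes without background subtraction or centring. Of the columns of per-sample values, 0 matched no sample.

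The signals were processed again with limma 3.58.1 in R 4.3.3. The function neqc, with negative controls inferred from the detection p-values and an offset of 16, corrected background, applied quantile normalization and gave log2 values. A probe was tested if its detection p-value was under 0.05 on at least 3 of the 6 arrays, which 17445 probes met. A gene without such a probe is given as not detected. The groups were compared with lmFit and eBayes, two-sided, without covariates, and p-values were adjusted over all tested probes by Benjamini-Hochberg with a threshold of 0.05. Log2 differences are producing minus non-producing. A 2-fold difference is an absolute log2 difference of at least 1. A gene was read from its tested probe with the highest mean signal over all arrays.

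Gene names came from the platform annotation and a gene table of the GRCm38.p6 assembly, which also gave the chromosome and the order of genes. One gene symbol was listed for 34885 probes and several for 18, while 10378 were not listed in the tables used here. Named probes covered 19057 genes, of which 9395 had a tested probe, 3633 of them more than 1. Of 1454 genes past the threshold with more than 1 tested probe, 829 had another probe past it in the same direction, and in 49 genes probes past it disagreed in direction. Of the tested probes, 2650 had no single symbol and were counted as probes only.

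A gene counted as detected in one hybridoma alone if its probe was detected on all 3 arrays of that group and none of its probes on any array of the other. For such a gene the fold is a lower bound, the mean of the detected group minus the mean of the other group after each of its arrays was raised to that array's lowest detected signal, which was 4.97 to 5.10 on the log2 scale.

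The test, the filter, the rule for naming genes, the alternatives and 27 gene lists were chosen before the data were examined. The lists were type 17 effector genes, type 17 regulators, type 1 helper genes, type 2 helper genes, regulatory T cell genes, cytotoxic and natural killer genes, the T cell receptor complex and its signalling, gamma delta and innate-like T cell genes, thymocyte and T-lymphoblast genes, markers of B cells, myeloid cells, fibroblasts and stroma, and erythroid cells and megakaryocytes, early response genes of T cell receptor stimulation, the NF-κB pathway and its targets, interferon-stimulated genes, homing and adhesion receptors, the TGF-β pathway, glycolysis and hypoxia, cholesterol synthesis, MHC class I and class II presentation, the cell cycle, apoptosis, the unfolded protein and amino acid stress response, sex-linked genes and housekeeping genes. Each list with at least 3 tested genes, 24 in all, was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists, and again with an estimated correlation. The test fry, which asks whether a list's genes move on balance one way and compares the list with no other genes, was run beside it.

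Named genes were Il17a and Il17f, the type 17 genes past the threshold, the 10 largest increases and 10 largest decreases among genes detected on all 6 arrays, the 5 largest bounds in each direction, and in every other list up to 4 genes past the threshold with the largest differences. Clone and predicted-gene names were left out of the ranking by fold and by bound. Probes without a symbol, members of the lists beyond this rule, and all genes named for their chromosome or as histones were picked after their values were seen.

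Alternatives covered the background correction, the normalization, the authors' processed values, the detection filter, the variance model, array weights, the replicate number as a block, each array left out, and the handling of several probes per gene. Comparisons by chromosome, and a fit with each chromosome's median difference removed, were chosen after seeing the data. Chromosome medians were tested against 10000 random gene sets, and running medians over 31 neighbouring genes against 500 random gene orders, over 9369 genes placed on 20 chromosomes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

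The steps were tested on simulated data built on the measured spread of the producing against non-producing comparison, with 9395 genes and 50 genes changed at each size. Of these, 54% were called at a log2 difference of 0.5, 70% at 1, 94% at 2 and 100% at 3, with 0 in the wrong direction. Of 9195 unchanged genes 7 were called, and 0 genes were called in a simulation without change. A shifted list and a shifted chromosome were called, and 0 others. Each simulated probe varied on its own. The simulation therefore does not show how often lists or chromosomes of correlated genes are called falsely.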

Results

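Total RNA from mouse hybridomas, lines made by fusing a lymphocyte with a tumour cell, was hybridized to Illumina mouse expression arrays. The 6 arrays formed 2 groups: 3 from a hybridoma that produced IL-17 and 3 from a hybridoma that did not. Each group carried a single clone name, so the comparison was between 2 hybridomas. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Mean signal per array was 559, 518 and 505 in the non-producing group and 454, 482 and 399 in the producing group, or 527 ± 28.5 against 445 ± 42.3 (SD, n = 3). A share of 38.5% ± 0.776 of the probes was above background on the non-producing arrays and 37.2% ± 0.253 on the producing arrays (SD, n = 3). Both measures separated the groups completely, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The number of arrays limits the precision of each value. All 6 arrays lay on 1 chip, with each group on its own block of neighbouring positions, so chip position and group cannot be told apart.

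The comparison asked which transcripts differed between the IL-17-producing and the non-producing hybridoma. The producing hybridoma had more Actn2, the actin cross-linker of the muscle Z-disc (19.9-fold), Slc6a13, a GABA transporter (10.6-fold), and Cd6, a lymphocyte surface receptor that modulates T cell receptor signalling (8.95-fold). Prkcz, an atypical protein kinase C (8.24-fold), Hes1, a transcriptional repressor induced by Notch (5.45-fold), and Ramp1, a subunit of the receptor for calcitonin gene-related peptide (5.13-fold), were higher as well. Lower were Igfbp4, which binds insulin-like growth factors, Ppic, a cyclophilin, Ednrb, the endothelin receptor type B, P2ry14, a receptor for UDP-glucose, Casp1, the caspase that processes IL-1β, and the chemokine Ccl5. Their log2 differences, producing minus non-producing, were -2.91, -2.79, -2.79, -2.78, -2.76 and -2.75.

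Neither Il17a nor Il17f, the cytokine genes that give the groups their name, was above background on any of the 6 arrays. The Il17a probe read 4.57 ± 0.05 on the log2 scale in the producing group and 4.62 ± 0.10 in the non-producing group (SD, n = 3), a difference of -0.05. The array's own detection test gave the Il17a probe p-values from 0.155 to 0.416. The Il17f probe read 4.35 ± 0.02 against 4.38 ± 0.05 (SD, n = 3), with detection p-values from 0.578 to 0.918. No fold is given for either gene because both groups were at background. The labels of the groups were therefore not checked by these transcripts.

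Of 9395 genes tested, 3448 passed an adjusted p of 0.05 (limma with Benjamini-Hochberg), 1703 of them higher and 1745 lower in the producing hybridoma. The median size of these differences was 0.47 on the log2 scale. A 2-fold difference was reached by 341 genes, 120 higher and 221 lower. That count depended on the processing, with 154 genes (57 higher) at an offset of 50 and no negative controls, 164 (62 higher) without background correction, 168 (65 higher) with the authors' processed values and 227 (82 higher) with detection required on all 6 arrays. The median standard deviation between arrays of a group was 0.12 over the tested probes. Correlations across probes were 0.995 to 0.997 between arrays of a group and 0.977 to 0.981 between arrays of different groups.

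**Figure D1:**
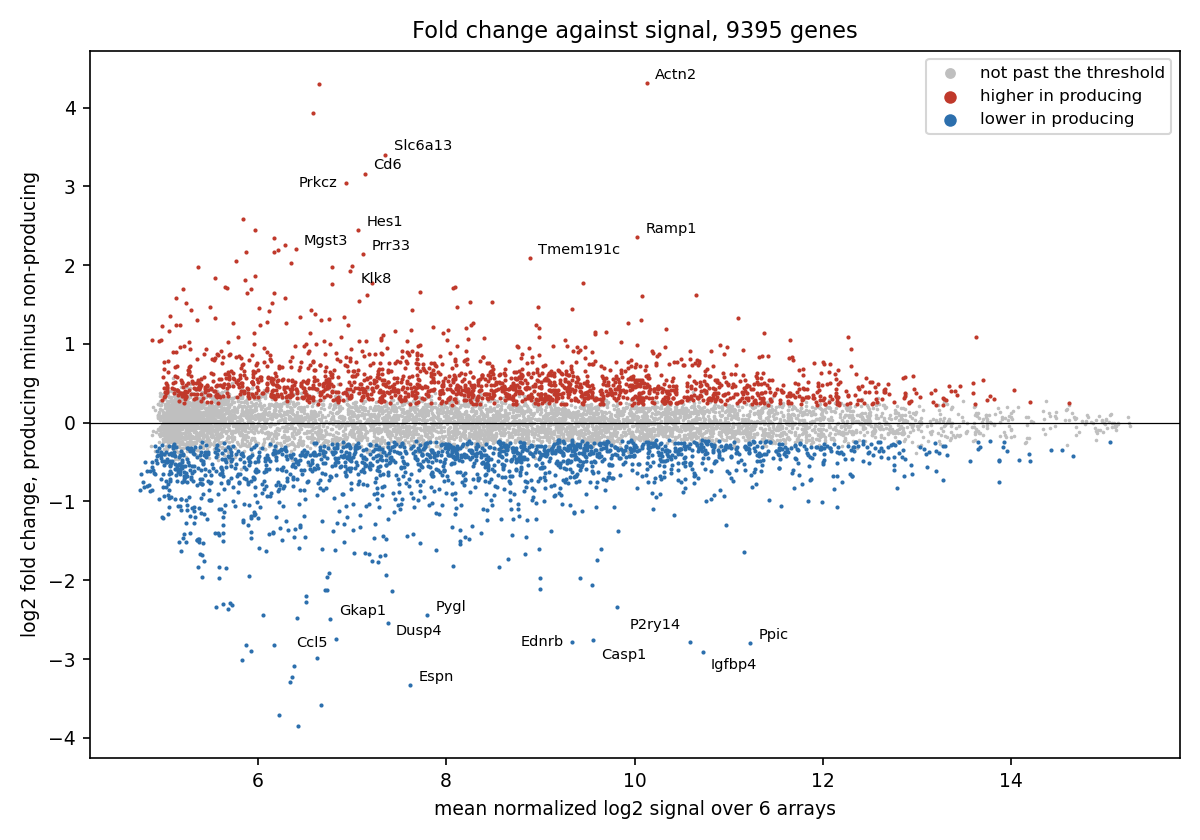
Log2 difference between the groups (producing minus non-producing) against the mean log2 signal of all 6 arrays, with 1 point per tested gene. Genes past the threshold are coloured, 1703 higher and 1745 lower, and the 10 largest increases and 10 largest decreases among genes detected on all 6 arrays are labelled.

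Actn2 had the largest difference among genes detected on all 6 arrays, 12.29 ± 0.05 against 7.97 ± 0.09 (SD, n = 3), and its second probe differed by 4.52. Its log2 difference was 4.31 with a standard error of 0.08 (limma, Benjamini-Hochberg adjusted p = 8.28e-08). Cd6 rose on all 3 of its probes, by 2.93, 3.12 and 3.16 on the log2 scale. The 10 largest increases went on with Mgst3, a microsomal glutathione S-transferase (2.20), Prr33 (2.14), Tmem191c (2.09) and Klk8, a secreted serine protease (1.99). Ppic varied little between replicates and had a log2 difference of -2.79 with a standard error of 0.07 (limma, Benjamini-Hochberg adjusted p = 1.70e-07). Ccl5 was the most variable of the genes that fell furthest, with 5.46 ± 0.41 in the producing group against 8.21 ± 0.01 in the non-producing group (SD, n = 3). Dusp4, a phosphatase of MAP kinases (-2.54), Gkap1, which binds cGMP-dependent protein kinase (-2.49), and Pygl, a glycogen phosphorylase (-2.44), completed the decreases together with Espn. The brightest probe of Espn, an actin-bundling protein, differed by -3.33, another probe by -1.03, and the remaining one by 0.21, which did not pass the test.

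**Figure D2:**
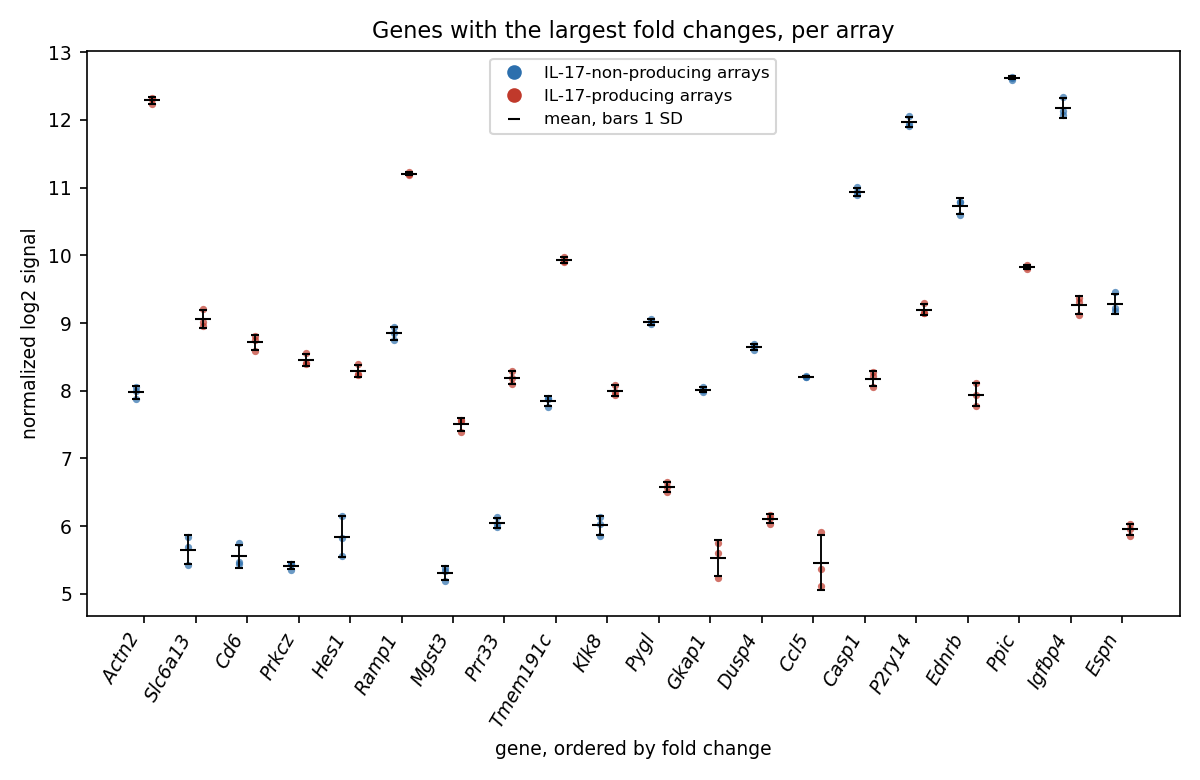
Normalized log2 signal of each array for the 10 genes with the largest increases and the 10 with the largest decreases among genes detected on all 6 arrays. Points are arrays (3 per group) and bars are group means with 1 standard deviation. Actn2 stood at 12.29 against 7.97 and Ppic at 9.83 against 12.62.

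Among genes past the threshold, a further set was above background on all 3 arrays of one hybridoma and on none of the other. It held 44 genes detected in the producing and 148 in the non-producing hybridoma. The producing arrays were the dimmer ones, with a mean signal of 445 against 527. Detected in the producing hybridoma alone were Art4, an ADP-ribosyltransferase family member (at least 11.6-fold higher), Gpx7, a glutathione peroxidase of the endoplasmic reticulum (at least 4.55-fold), Lurap1l (at least 4.37-fold), Gpr146 (at least 3.87-fold) and the basic helix-loop-helix factor Lyl1 (at least 2.87-fold). Detected in the non-producing hybridoma alone were Scamp1, a carrier membrane protein of the secretory route (at least 10.4-fold lower in the producing hybridoma), the C-type lectin Clec2i (at least 9.64-fold), Cd160, a receptor of natural killer and T cells (at least 7.49-fold), Slc7a11, the cystine-glutamate exchanger (at least 7.47-fold), and the E protein Tcf4 (at least 7.19-fold). By the rule for this set, all 10 had passed the test (limma with Benjamini-Hochberg). Among probes without a single gene symbol in the annotation used, 743 passed and 73 of these differed by 2-fold or more. Probe ILMN_1225132 was detected in the non-producing hybridoma alone (at least 79.9-fold lower in the producing one). Probe ILMN_2521748 read 10.79 ± 0.10 in the producing group and 4.74 ± 0.32 in the non-producing group (SD, n = 3), where it was detected on 1 of the 3 arrays.

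Most type 17 effector genes were not detected, and the regulators went both ways. Of 14 type 17 effector genes, 5 could be tested and 9, Il17a and Il17f among them, were not detected. Il17re, a receptor subunit for IL-17C, rose by 0.91 on the log2 scale, with 2 of its 3 probes past the test, and the other 4 genes did not pass. Of 18 tested regulators, 6 rose, 5 fell and 7 did not pass, and 11 passed when adjusted over the list alone. Ikzf3, which encodes Aiolos (0.86, with its other probe at 0.43 not past the test), Arid5a, an RNA-binding protein (0.78), and Runx1 (0.49) rose. With each chromosome's median difference removed, an alternative chosen after seeing the data, Runx1 was at 0.25 and no longer passed (limma adjusted p = 0.113). Socs3, the inhibitor of signalling through STAT3 (-1.35), Irf4 (-1.03) and Id2 (-0.39, with 1 of its 3 probes at 0.07 and not past the test) fell. Smaller differences were seen for Bhlhe40 (0.37), Il6ra (0.33, other probe 0.17 and not past) and Stat3 (0.31, all 3 probes past the test). Also small were those of Fosl2 (-0.27) and Rbpj (detected in the non-producing hybridoma alone, at least 1.09-fold lower). The list had a median of -0.01 and a camera adjusted p of 0.927, and the effector list had a camera adjusted p of 0.708. Fry called 13 of the 24 lists, that of housekeeping genes among them, and had the effector list higher (fry adjusted p = 0.0168). For the regulators fry pointed down (fry adjusted p = 0.0517).

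The 5 smaller differences among the type 17 regulators lay near the threshold, and each lost its call when any 1 of several arrays was left out. Bhlhe40 lost its call without non-producing array 2 or 3 or producing array 2 or 3 (limma, Benjamini-Hochberg adjusted p 0.0695 to 0.101). Rbpj did so without non-producing array 2 or 3 or producing array 1 or 3 (0.0512 to 0.0773), and Stat3 without non-producing array 2 or producing array 1 or 3 (0.0572 to 0.0614). Il6ra lost it without any array other than non-producing array 1 (0.0503 to 0.0911), and Fosl2 without any array other than producing array 2 (0.0509 to 0.0717).

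Genes of other T cell programmes also went both ways. Of 4 tested type 1 helper genes, Il12rb1, a subunit of the IL-12 receptor (0.36), and Stat4 (0.33) rose and Ccl5 fell. The other probes of Il12rb1 and Stat4, at 0.18 and 0.20, did not pass. The median of that list was 0.20, its mean -0.50, and its camera test pointed up (adjusted p = 0.904) while fry pointed down. Of 5 type 2 helper genes, the chemokine receptor Ccr8 fell (-0.36) and 4 did not pass, with a median of 0.07, a mean of -0.04 and a camera adjusted p of 0.989. Stat4 lost its call without non-producing array 1 or 3 or producing array 1 or 3 (limma adjusted p 0.0768 to 0.0930), and Ccr8 without non-producing array 2 or 3 or producing array 2 (0.0604 to 0.0765). Of 6 regulatory T cell genes, 2 rose, 3 fell and 1 did not pass, and all 6 passed when adjusted over the list alone. Nrp1, the receptor neuropilin 1 (-1.75, all 3 probes), and Nt5e, the ectonucleotidase CD73 (-1.38), fell and Tnfrsf4, the receptor OX40, rose (0.65). The list had a camera adjusted p of 0.708, while fry had it lower on balance (fry adjusted p = 0.00024). Of 3 cytotoxic and natural killer genes, the cathepsin gene Ctsw rose (0.57), 2 did not pass, and 2 passed when adjusted over the list alone (camera adjusted p = 0.708). Ctsw was at 0.26 with chromosome medians removed and did not pass (limma adjusted p = 0.0978).

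Among 22 genes of the T cell receptor complex and its signalling, 6 rose, 8 fell and 8 did not pass, and 15 passed when adjusted over the list alone. Cd6 and the transcription factor gene Nfatc1 (1.26, with 1 of its 4 probes at 0.11 and not past) rose, and Cd3d, a subunit of the receptor complex (1.99-fold lower), and the costimulatory receptor gene Cd28 (log2 difference -0.75) fell. The list's median was -0.17 and its mean 0.02, and camera pointed down (adjusted p = 0.708) where fry pointed up. Of 7 gamma delta and innate-like T cell genes, 2 rose, 2 fell and 3 did not pass (camera adjusted p = 0.711). The costimulatory receptor gene Cd27 rose by 2.17 on its brightest probe while its other probe, at 0.10, did not pass, Sox13 rose by 1.28 and Sox4 fell by 0.91. Il17rb, which encodes a receptor subunit for IL-25, was at -0.26 and lost its call without any array other than producing array 1 (limma adjusted p 0.0650 to 0.0903) or with chromosome medians removed (-0.15, adjusted p = 0.181). Of 13 thymocyte and T-lymphoblast genes, 3 rose (Hes1, Lyl1 and Notch1), 4 fell and 6 did not pass, and 9 passed when adjusted over the list alone (camera adjusted p = 0.731). Lef1, a transcription factor of the Wnt pathway (-1.29), and Cd1d1, which presents lipid antigens (-1.10), were among those that fell.

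Few markers of other cell types were above background. Of 3 tested B cell markers, Vpreb1, a surrogate light chain gene, rose (0.51), Pou2af1, a coactivator of octamer factors, fell (-0.78) and 1 did not pass (camera adjusted p = 0.783). Vpreb1 was at 0.27 with chromosome medians removed and did not pass (limma adjusted p = 0.137). Of 17 myeloid markers with a probe, 16 were not detected, and Lyz1, a lysozyme gene, was detected in the non-producing hybridoma alone (at least 1.43-fold lower in the producing one). Of 13 fibroblast and stromal markers with a probe, 11 were not detected, 1 did not pass and Pdgfrb rose (0.49), a call lost without non-producing array 1 or 2 or producing array 2 or 3 (limma adjusted p 0.0821 to 0.0970). Of 12 erythroid and megakaryocyte markers, 10 were not detected and 2 did not pass.

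Genes of antigen presentation by MHC class I were mostly higher. Of 14 tested, 10 rose, 0 fell and 4 did not pass, 11 rose when adjusted over the list alone, and the median was 0.64 on the log2 scale (camera adjusted p = 4.13e-05). With an estimated correlation between genes the list had an adjusted p = 0.465. Psmb9, an immunoproteasome subunit (1.60), H2-T23, a nonclassical class I gene (1.46), the class I heavy chain gene H2-K1 (1.24) and Tapbp, which encodes the loading factor tapasin (1.14), rose most. Heavy chain genes of this family are alike in sequence, so which of them a probe reads is uncertain. Of the 14 genes, 10 lie on chromosome 17 of the GRCm38.p6 assembly, whose genes were on balance higher in the producing hybridoma. These 10 had a median of 0.93 with 9 higher, and the other 4 a median of 0.14 with 1 higher. With chromosome medians removed the list had a median of 0.42 and a camera adjusted p of 0.000547. That fit takes out only the median of a whole chromosome. A stretch of 176 neighbouring genes on chromosome 17, described below, had a median of 0.39 against 0.30 for the chromosome. The fit therefore does not separate this list from the position of its genes. Of 4 MHC class II presentation genes, H2-Oa, also on chromosome 17, rose (0.37, other probe 0.17 and not past) and 3 did not pass (camera adjusted p = 0.757). H2-Oa was at 0.06 with chromosome medians removed and did not pass (limma adjusted p = 0.578).

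The unfolded protein and amino acid stress response was the other list called. Of 22 tested genes, 8 rose, 2 fell and 12 did not pass, 10 passed when adjusted over the list alone, and the median was 0.19 (camera adjusted p = 0.0275). With an estimated correlation this list, too, had a camera adjusted p = 0.465, so neither of the 2 calls among 24 lists held there. The estimate was 0.14 for the MHC class I list but -0.01 for the stress response list, under the preset 0.01. A higher correlation between genes therefore does not account for the lost stress response call. Sdf2l1, a chaperone complex component of the endoplasmic reticulum (1.13), Shmt2, the mitochondrial serine hydroxymethyltransferase (0.73), Ddit4, an inhibitor of mTORC1 (0.62), and the pseudokinase gene Trib3 (0.47, with the other probes at 0.42 and 0.31 not past the test) rose. When the arrays were scaled to a common median in place of quantile normalization, the list had an adjusted p of 0.0557.

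**Figure D3:**
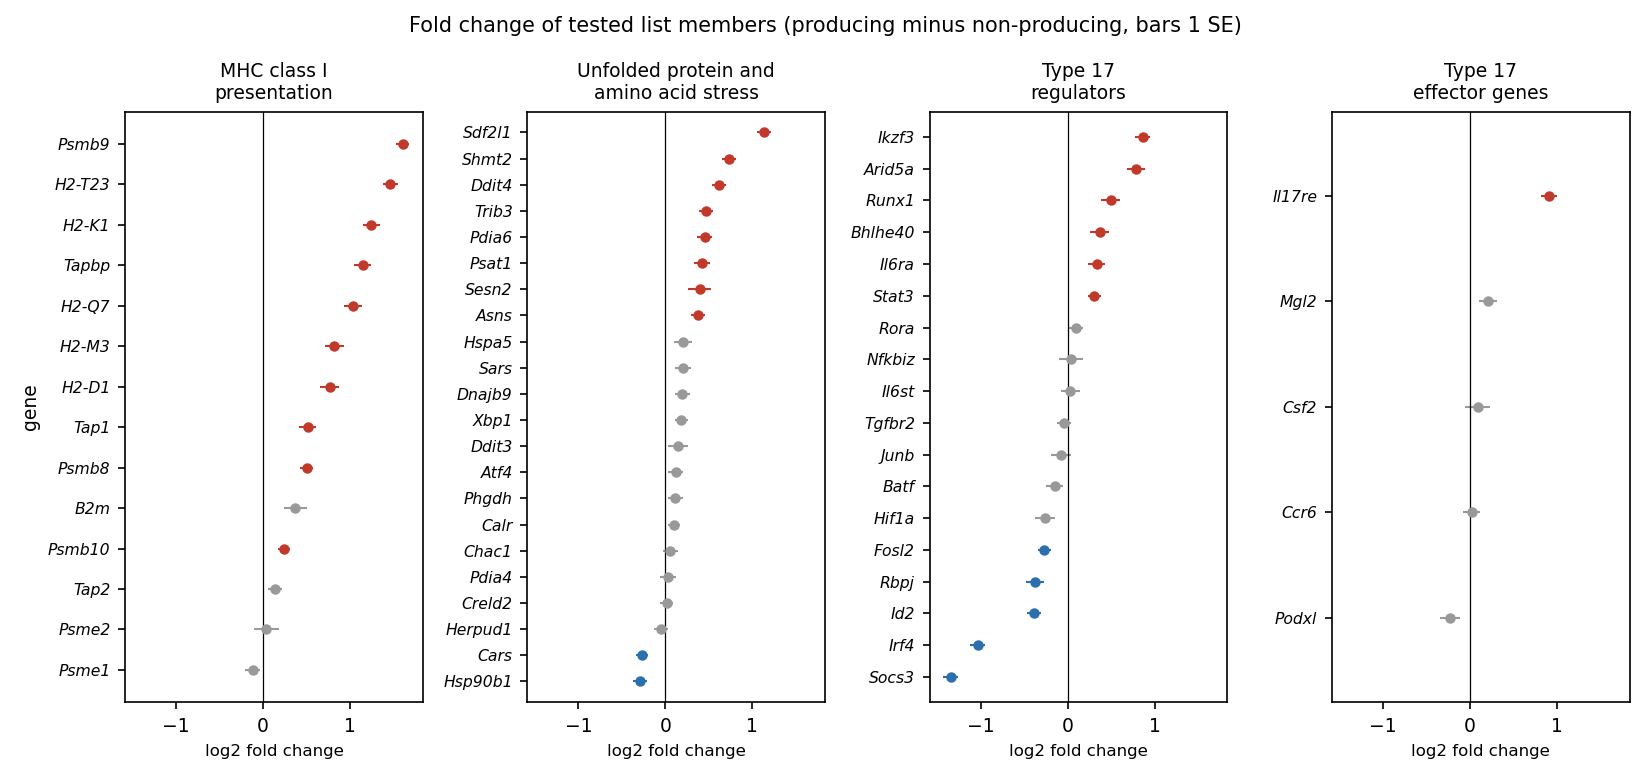
Log2 difference between the groups (producing minus non-producing) of each tested gene in 4 of the fixed lists. Points are genes with bars of 1 standard error, red where the gene rose, blue where it fell and grey where it did not pass. Rbpj, at background in the producing group, is shown at its fitted difference. Of 14 MHC class I genes 10 rose, and of 22 stress response genes 8 rose. The type 17 regulators went both ways, and 1 of 5 type 17 effector genes rose.

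Signalling lists were mixed. Of 10 early response genes of T cell receptor stimulation, Tnf rose (0.47), Irf4, Il2 (-0.93) and Egr1 (-0.71) fell and 6 did not pass (camera adjusted p = 0.708). Of 14 NF-κB pathway genes and targets, 7 rose, 2 fell and 5 did not pass (camera adjusted p = 0.322). Ltb, which encodes lymphotoxin beta (1.54), and the inhibitor gene Nfkbie (0.69) rose and Relb fell (-0.65), and Ltb, Nfkbie and Tnf all lie on chromosome 17. Bcl3 was detected in the non-producing hybridoma alone (at least 1.29-fold lower). Of 13 interferon-stimulated genes, 3 rose, among them Ifi47 (1.16) and Bst2 (0.93), 3 fell, among them Isg20 (-0.76) and Usp18 (-0.41, other probe -0.23 and not past), and 7 did not pass (camera adjusted p = 0.731). Of 13 homing and adhesion receptors, 2 rose, 3 fell and 8 did not pass, and 7 passed when adjusted over the list alone (camera adjusted p = 0.708). Itgal, the alpha chain of the integrin LFA-1, fell (-0.72) and the integrin chain Itgb7 rose (0.46). Of 12 genes of the TGF-β pathway, its inhibitor Ski rose (0.51), 4 fell, among them the related gene Skil (-0.80) and the ubiquitin ligase gene Smurf1 (-0.62), and 7 did not pass (camera adjusted p = 0.322). With chromosome medians removed Tnf was at 0.17, Nfkbie at 0.39 and Ski at 0.23, and none of the 3 passed (limma adjusted p = 0.182, 0.0767 and 0.106).

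Of 19 glycolysis and hypoxia genes, 5 rose, 2 fell and 12 did not pass, and 8 passed when adjusted over the list alone (camera adjusted p = 0.921). Vegfa was detected in the producing hybridoma alone (at least 2.32-fold higher), and the prolyl hydroxylase genes P4ha1 (-0.76) and Egln3 (-0.51) fell. Of 15 cholesterol synthesis genes, Mvd rose (0.48), 4 fell, among them Mvk (-0.43), Lss (-0.41) and Sqle (-0.40, other probe -0.03 and not past), and 10 did not pass (camera adjusted p = 0.708). Of 30 cell cycle genes, 7 rose, 3 fell and 20 did not pass (camera adjusted p = 0.708). Cdkn2a, the locus of 2 cell cycle inhibitors, rose on all 3 probes (1.16 on the brightest), Ccnd3 rose (0.67), and Cdk6 (-0.89) and Ccnd2 (-0.61) fell. Of 18 apoptosis regulators, 9 rose, 3 fell and 6 did not pass, and 14 passed when adjusted over the list alone (camera adjusted p = 0.663). Casp9, the initiator caspase of the mitochondrial route (0.98), and Bad (0.57) rose and Casp1 fell. Of 7 sex-linked genes, Eif2s3x was lower (-0.33) and 6 did not pass, the Y-linked Eif2s3y, Kdm5d and Uty among them (camera adjusted p = 0.708). Of 11 housekeeping genes, the ribosomal protein genes Rplp0 (1.30) and Rpl13a (0.75) and Tbp (0.45) rose, Hprt was at -0.43 with 1 of its 3 probes past the test, and 7 did not pass (camera adjusted p = 0.708). Tbp was at 0.15 with chromosome medians removed and did not pass (limma adjusted p = 0.228).

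Tested genes were also compared by chromosome, in the GRCm38.p6 assembly, a comparison chosen after the data had been seen. Genes of chromosomes 4, 16, 17 and 19 were on balance higher in the producing hybridoma, with medians of 0.27, 0.24, 0.30 and 0.31 on the log2 scale over 580, 295, 481 and 331 genes. These 1687 genes, 18.0% of those tested, held 817 of the 1697 placed genes that rose and 88 of the 1741 that fell. Chromosome 3 had the lowest median, -0.19 over 448 genes, with 34 higher and 176 lower. For these 5 chromosomes the permutation p, from 10000 random gene sets of each chromosome's size, was 0.0001, the smallest they can give, or 0.0002 after Benjamini-Hochberg adjustment over 20 chromosomes. Genes are not independent replicates, so this test compares a chromosome with random sets of genes on the same arrays. In all, 13 of the 20 chromosomes had an adjusted permutation p under 0.05, the 4 with higher genes and 9 with medians below 0. Of these 9, chromosome 3 apart, the medians were -0.04 to -0.11, and tested genes outside the 4 chromosomes together had a median of -0.05. The test compares each chromosome with all placed genes, the 4 chromosomes included. Medians near -0.05 are therefore not low against the remaining chromosomes. Chromosomes 7, 14, 15 and X, at -0.09, -0.11, -0.09 and -0.08, also had a permutation p of 0.0001.

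With chromosome medians removed, 11 named genes in all lost their calls (limma, Benjamini-Hochberg adjusted p 0.0502 to 0.578). Beside those given above, they were the apoptosis regulator Bak1 and the integrin chain Itgb1. Bak1 moved from 0.66 to 0.35 (limma adjusted p = 0.149). Itgb1, whose other probe at -0.45 had not passed, moved only from -0.41 to -0.40 (limma adjusted p = 0.0502). Bak1 also lost its call without non-producing array 1 or 3 (limma adjusted p 0.0543 to 0.0603), and Itgb1 without non-producing array 1 or 2 or producing array 1 or 2 (0.103 to 0.118).

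**Figure D4:**
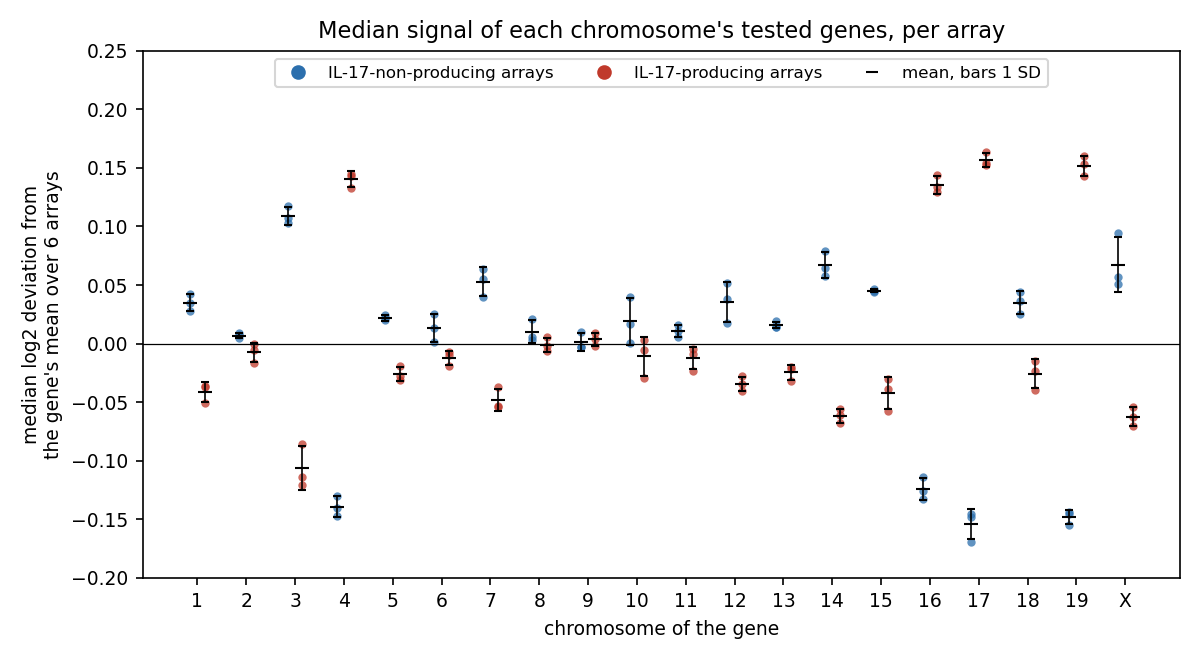
Median over each chromosome's tested genes of the log2 deviation from the gene's mean over the 6 arrays. Points are arrays (3 per group) and bars are group means with 1 standard deviation; the producing arrays averaged 0.14, 0.14, 0.16 and 0.15 on chromosomes 4, 16, 17 and 19 and -0.11 on chromosome 3.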

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

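Removal of the chromosome medians was the alternative chosen after seeing the data; the others were planned. The cause of the changes below was not tested, except where fewer or more values were counted by construction. Where a gene is at background in one group, only a bound on its fold can be given. All 111 named genes past the threshold, which leaves out Il17a and Il17f, kept their direction in each alternative that tested them and 90 also their side of the threshold; of 1981 pairs of gene and alternative, 1902 kept their call, 79 fell short of it and 0 reversed. Genes past the threshold numbered 3448, and 5906 when probes were counted; with 1 array left out they ranged from 2644 to 2976. The 341 genes at 2-fold became 154 with an offset of 50 and no negative controls, 164 without background correction, 168 with the authors' processed values, 227 with detection required on all 6 arrays and 535 as probes, and 339 to 354 with 1 array left out. Higher genes numbered 1703, or 2961 as probes and 1309 to 1484 with 1 array left out. Of the 120 higher at 2-fold, the counts were 57, 62 and 65 under the first 3 of those settings, 204 as probes, and 120 to 127 with 1 array left out. For Il17a, at -0.05 and at background on all arrays, scaling to a common median gave 0.23, and leaving out 1 array -0.08 to 0.01. The 2 called lists became 1 with median scaling, 0 with an estimated correlation and 13 with fry, which asks another question, and stayed 2 with any 1 array left out. Scaling to a common median moved the median of all probes to 0.06, and 55.4% of the called genes were then higher against 49.4%. With chromosome medians removed, 2889 genes passed and 304 at 2-fold, 2542 of the called genes were shared, both lists were called, and 11 of the 111 named genes lost their call (Bak1, Ctsw, H2-Oa, Il17rb, Itgb1, Nfkbie, Runx1, Ski, Tbp, Tnf and Vpreb1, of which Itgb1 hardly moved in size). With the replicate number as a block 3019 genes passed, but the numbers do not pair the arrays: correlations of arrays with the same number across groups, after group means were removed, were -0.04, -0.16 and 0.09, and 1 of the 3 numbers had its own partner as the best. A slide block was not run, because all arrays were on 1 slide.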

Other observations

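Tests in this part were chosen only after the result was seen, except for the comparison with genes of matched signal and the counts over other splits of the arrays. Replication-dependent histone genes were in none of the lists, were picked after their values were seen and were not tested as a set. Of 48 tested, 34 rose, 0 fell and 14 did not pass (limma with Benjamini-Hochberg), with a median of 0.56 on the log2 scale and the lowest value, -0.25, in H2bc4. H3c3 rose by 1.18 and H4c2 by 1.03. Under the other background corrections and scalings the median was 0.45 to 0.58 and 34 to 35 rose, while with an offset of 50 and no negative controls 1 of them fell. On chromosome 13 lay 39 of the 48, and a stretch from H4c18 to H2ac4 held 31 tested genes, 26 of them histone genes, with 21 higher and 0 lower. These genes are near copies of each other, so which of them a probe reads is uncertain.

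Neighbouring genes on chromosome 3 were on balance lower in the producing hybridoma. Stretches, that on chromosome 13 included, were bounded where the running median went below -0.29 or above 0.29, limits taken from random gene orders. Medians and counts within a stretch follow in part from that choice. A stretch of 72 tested genes from Il2 to Gucy1a1 had a median of -0.51, with 51 lower and 0 higher past the test (limma with Benjamini-Hochberg). Its members included P2ry14 (-2.78), Mlf1 (-1.65), the phosphatase gene Ppm1l (-1.19), Lxn, a carboxypeptidase inhibitor (-1.09), Nmd3, an export factor of the large ribosomal subunit (-1.08), the T cell growth factor gene Il2 (-0.93) and the transcription factor gene Foxo1 (-0.80). Slc7a11, detected in the non-producing hybridoma alone, lies there as well. A second stretch of 60 genes on chromosome 3, from Ttc24 to Ints3, had a median of -0.35 with 34 lower and 2 higher. Over all chromosomes 15 stretches were lower and 38 higher, the higher ones on 5 chromosomes. The longest were higher, with 176 genes on chromosome 17 (median 0.39) and 115 on chromosome 19 (median 0.42). Lower stretches outside chromosome 3 held at most 16 genes, on chromosome 7.

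Tested genes of chromosomes 4, 16, 17 and 19 were on balance higher in the producing hybridoma. Random gene sets of the same sizes gave an adjusted permutation p of 0.0002 for each, which argues against a chance arrangement, and against genes of matched signal the smallest shift was 0.27, which argues against a trend with signal as the whole cause, although the shift was 0.08 to 0.20 in the dimmest of 4 equal classes of signal and 0.31 to 0.47 in the others. Genes with a second probe had a median of 0.28 on that dimmer probe, so variants under single probes do not account for the shift, and with each chromosome divided at its middle gene, the smallest median of a part was 0.23, so both parts of each chromosome shared it. A candidate explanation is a difference in the number of copies of these chromosomes between the hybridomas, as a hypothesis, since no DNA was measured. Regulation of many genes by the state that gives IL-17 production was not tested and stays open. An effect of chip position on probes whatever their chromosome would shift random gene sets alike. The permutation p of 0.0001 for each of the 4 chromosomes argues against it as the cause of this pattern. For single genes, chip position cannot be told apart from the group.

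The chromosome 3 stretch was weighed against chance and against a shift of the whole chromosome. Among 500 random gene orders a share of 0 reached its lowest running median of -0.65, the lowest being -0.35. When chromosome 3's own genes were put in 500 random orders, which keep a shift of the whole chromosome, a share of 0 reached -0.65 and the lowest was -0.56, which argues against a uniform shift of the chromosome. Whether copies of this segment differ between the hybridomas, or its genes are regulated together, was not tested, and no DNA was measured.

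Il17a and Il17f were not above background on any array, although 1 group is labelled as producing IL-17. If the RNA was taken from cells that were not stimulated, which the labels do not say, genes that T cells switch on after stimulation would be mostly undetected. Of 38 type 17 effector and early response genes with a probe, 18 were detected on no array, 14 on all 6 and 6 on some. Il17a and Il17f, the genes to be explained, are among the 18. The effector list was not drawn up as genes that stimulation switches on. It also holds receptor genes, such as Il17re and Ccr6, detected on all 6 arrays, and Il23r and Il1r1, detected on 0. The joint count is therefore a poor measure of stimulation. By the filter used for testing, 9 of the 14 effector genes and 14 of the 24 early response genes were not detected. These counts decide neither way. Rest at harvest may account for the missing Il17a and Il17f signal and cannot be told apart from a low sensitivity of their probes, of which each gene had 1.

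Of the 10 ways to split the 6 arrays into 3 and 3, which are too few for a share under 0.05, 1 gave as many genes past the threshold, the real one, with 3448 against at most 0 in the others. For genes at 2-fold it was again 1 of 10, with 341 against at most 0. For called lists it was 1 of 10, with 2 against at most 1. Every other split mixed arrays of both hybridomas in each group, which adds the difference between hybridomas to the spread within groups. Low counts there were built in, so the splits decide nothing about chance.

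Of the 341 genes at 2-fold, a count that fell to 154 to 168 under the other background settings and with the authors' processed values and to 227 with detection required on all 6 arrays, 221 were lower. Of the 135 such genes whose brighter group had a mean of at least 8.05 on the log2 scale, 85 were lower and 50 higher. The other group could still be at background. Clec2i read 4.50 in the producing group and Art4 4.62 in the non-producing group. This count therefore does not leave out genes at background in 1 hybridoma.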
